A study of Homo sapiens with 15 samples.

How the data were processed

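RNA was measured in 15 libraries of T47D cells in 5 groups of 3: parental cells on vehicle (PAR vehicle) and resistant cells on vehicle (TR vehicle), 4-OHT (TR 4-OHT), erdafitinib (TR erdafitinib) or both (TR combination). Per the labels' protocols, cells were seeded for 24 h, kept for 48 h in charcoal-stripped serum and treated for 120 h with 1 µM 4-OHT, 5 µM erdafitinib, both, or 0.05% DMSO, and paired-end libraries were made from total RNA with a stranded kit. The labels call the 3 libraries of a group biological replicates and say no more on how they were made. The p-values therefore measure only the spread between these samples, which may be technical. Reads were aligned with HISAT2 2.1.0 to GRCh38, per the submitters' processing notes. The deposited values are raw counts per Ensembl gene made with featureCounts 2.0.1, paired-end and reverse-stranded, with the Ensembl 104 annotation, per the file headers. The submitters' processing notes give featureCounts 1.4.6-p1 instead. Reads that matched several places or genes were left out by default, per the file headers' command line. Read trimming and quality filtering were not given in the sources used here.

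Each file held 60664 gene IDs, of which 60463 had a symbol. Gene type and transcript GC content came from GENCODE release 29, which covered 58396 of the IDs and may differ from the annotation used for counting. Totals ranged from 6946684 to 28717380 counts (median 22304029), mitochondrial genes held 14.5 to 25.7% of counts, and 3 counts in a library equalled 0.105 to 0.432 CPM. Counts of libraries of the same group differed by more than counting error, with a chi-square per gene of 8.05 to 164, so no library was a copy of another of its group.

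The groups, comparisons, tests, gene lists, named-genes rule and most alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 5 groups (16210 kept, 44454 left out) and scaled by TMM (factors 0.907 to 1.102). All 15 libraries entered 1 quasi-likelihood fit with a mean per group and no block, with 10 residual degrees of freedom and a common dispersion of 0.09505. The quasi-likelihood F test was run for each comparison, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from F as the absolute log2 fold change over its square root. CPM values use TMM-scaled totals and are given as mean ± SD of 3 libraries. A gene with 0 counts in a group was compared against 3 counts over that group, and a gene with 1 to 3 counts was given as a ratio with an exact 95% counting interval. Intervals and floors cover counting error only.

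The 17 lists were ER target genes, luminal identity, epithelial junction, mesenchymal EMT, FGFR system, MAPK feedback, receptor tyrosine kinases, S phase, G2 and mitosis, cholesterol synthesis, lysosome, interferon response, ATF4 and unfolded protein response, p53 targets, YAP targets, basal epithelium, and markers of other cell types. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over all lists and comparisons together. The rule for named genes took, per comparison, the 5 largest rises and falls among called protein-coding genes with an average log2 CPM of at least 2 and groups that did not overlap. It added FGFR1 to FGFR4, ESR1, PGR, VIM, CDH1 and DUSP6. It also added the 3 members with the smallest p of up to 5 lists with the smallest camera p, and of the mesenchymal, junction, ER target and MAPK feedback lists. For the interaction it took the 5 genes with the smallest p. All called named genes had groups that did not overlap, except FGFR4 in TR against PAR. With 3 libraries against 3, such a separation arises by chance in 10% of genes. The chance overlap of 2 lists of calls was n1 × n2 / N per direction.

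The alternatives were size factors by DESeq2's method in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter at CPM of at least 1 in 3 libraries, only the groups compared in the fit, the replicate number as a block, a test against a 1.5-fold change (glmTreat), counts thinned to the lowest total, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were added. Alternatives chosen after seeing the data were a correction for GC content and length, the first within-group axis as a covariate, and leaving out the 2 shallowest libraries (PAR 2 and TR 4-OHT 2). Scripts were tested on simulated counts with the real means and library sizes and 200 changed genes in each of 3 draws. Of 4-fold changes, edgeR called 57.7% for TR vehicle against PAR vehicle, 63.1% for 4-OHT against vehicle, 67% for erdafitinib against vehicle, 66.8% for the combination against 4-OHT, 65.3% for the combination against erdafitinib and 36.4% for the interaction. Of 2-fold changes it called 17.6%, 14.5%, 13.9%, 19.3%, 18.5% and 2% in the same order, and of 1.5-fold changes 1.5%, 2.5%, 0%, 1%, 2% and 0%. False calls made up 1.2 to 7.4% of all edgeR calls, against 28 of 106 DESeq2 calls for 4-OHT against vehicle and 18 of 90 for the combination against 4-OHT, in 1 draw each. In a simulated comparison of the combination with 4-OHT, camera called a list of 22 genes raised 1.5-fold and 1 of 15 unchanged lists. In these simulations genes were drawn independently, without the variation that real libraries share across genes. The shares called, the rates of false calls for both tools and the camera result may therefore not carry over to the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Splicing, allele-level reads and genes outside the count tables were not analysed here. Results of 4 genes are not reported here.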

Results

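Gene expression was measured by RNA sequencing in T47D cells, an established luminal breast cancer line that depends on the oestrogen receptor (ER), and in a derivative resistant to 4-hydroxytamoxifen (4-OHT), the active metabolite of the anti-oestrogen tamoxifen. Parental cells (PAR) received vehicle (0.05% DMSO). Resistant cells (TR) received vehicle, 1 µM 4-OHT, 5 µM erdafitinib (a kinase inhibitor of the fibroblast growth factor receptors, FGFRs) or both drugs, for 120 h. Each of the 5 groups held 3 libraries, 15 in all. The series title sets out the question, which is how FGFR inhibition relates to endocrine resistance and to genes of the epithelial-mesenchymal transition (EMT). Total counts ranged from 6946684 in PAR 2 to 28717380 in TR erdafitinib 2, with a median of 22304029, and TR 4-OHT 2 held 8990899. A gene with 3 counts in a library stood at 0.105 to 0.432 CPM (counts scaled to library size), depending on the library. For a gene at 0 in a group, the floor used was 3 counts over the whole group. Intervals and floors cover counting error only. After filtering, 16210 genes were tested.

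Libraries of the same group differed along 1 main axis, which held 73.4% of the within-group variance and ran with the GC content of the transcripts (Spearman 0.809 across genes, which are not independent replicates). The fifth of genes with the highest GC content (median 59.9%) deviated from the group mean by between -0.98 in TR vehicle 1 and 0.78 in PAR 3 on the log2 scale. The common biological coefficient of variation was 30.8%.

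**Figure D1:**
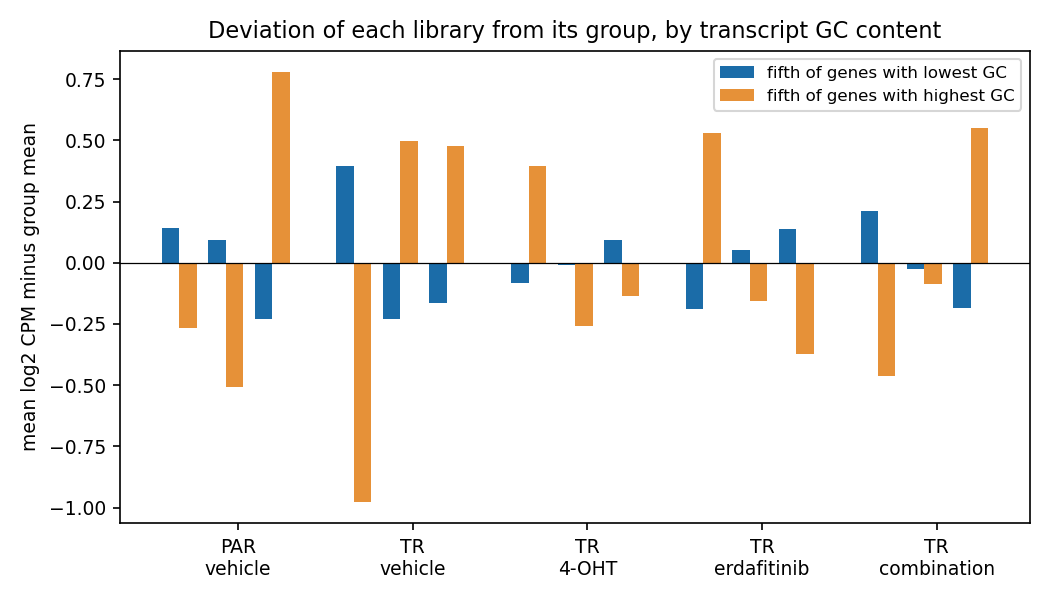
Mean deviation of each library (3 pairs of bars per group, replicates 1 to 3 from left to right) from its group mean in log2 CPM, for the fifth of genes with the lowest (blue) and the highest (orange) transcript GC content. The highest-GC genes range from -0.98 in TR vehicle 1 to 0.78 in PAR 3.

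Resistant and parental cells on vehicle were compared to describe the resistant state. Genes induced by oestrogen were far lower in resistant cells. GREB1, an ER cofactor and target gene (ENSG00000196208, chromosome 2, 11482341 to 11642788), stood at 486 ± 36.3 CPM (SD, n = 3) in PAR and 13.1 ± 1.398 CPM in TR, a log2 fold change of -5.22 (SE 0.20; adjusted p = 4.26e-10, edgeR quasi-likelihood test). PGR, the progesterone receptor gene, fell by 4.62 (SE 0.27) on the log2 scale, from 3863 ± 987 to 157 ± 49.4 CPM (adjusted p = 1.74e-08). The ubiquitin ligase gene SIAH2 fell by 3.58 on the log2 scale and the potassium channel gene KCNK5 by 8.00. ESR1, which encodes ERα (ENSG00000091831, chromosome 6, 151656691 to 152129619), fell less, by 1.44 (SE 0.16) on the log2 scale, and remained at 212 ± 33.7 CPM against 576 ± 93.6 in PAR (adjusted p = 7.39e-06). Of the 28 ER target genes tested, 17 fell and 1 rose, with 18 and 1 adjusted over the list alone, and the median log2 fold change was -1.80 (camera adjusted p = 3.74e-17). The riser was RET, a receptor tyrosine kinase gene (log2 fold change 4.05). Luminal identity genes did not pass as a list (camera adjusted p = 0.391, median 0.17 but mean -0.06): 4 of 17 rose, among them the transcription factor gene TBX3 (3.25), and 8 fell, among them FOXA1 (-1.25), which encodes a pioneer factor for ER. The counts for this list were the same adjusted over the list alone.

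**Figure D2:**
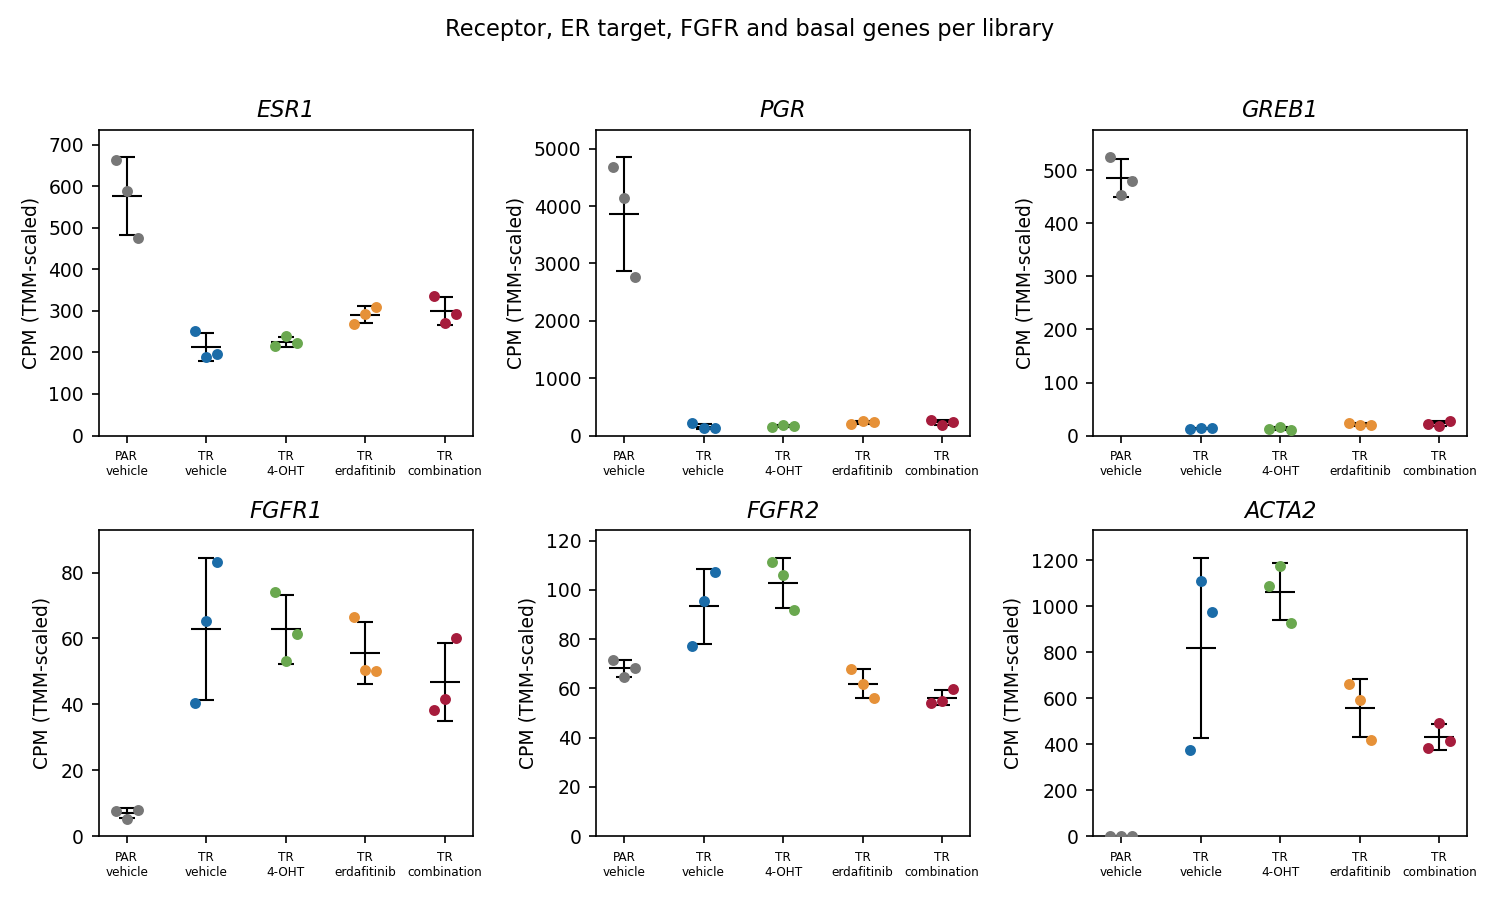
CPM (TMM-scaled) of 6 genes in the 5 groups, with each library as a point and the mean ± SD (n = 3) as bars. ESR1, PGR and GREB1 are lower and FGFR1 and ACTA2 higher in all 4 resistant groups than in PAR, and FGFR2 is lower in both groups with erdafitinib than in TR on 4-OHT (61.8 and 56.2 against 103 CPM).

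Genes of mesenchymal and of basal or myoepithelial cells were higher in resistant cells. SPARC, which encodes a secreted matrix protein, rose from 0.0522 ± 0.0456 to 214 ± 66.8 CPM; with 3 counts in all of PAR the ratio was 3392 (95% counting interval 1160 to 16400). TNC, the tenascin C gene, had 1 count in PAR and 105 ± 32.1 CPM in TR, a ratio of 5008 (899 to 198000). The actin-binding protein gene CALD1 rose by 7.30 (SE 0.45; adjusted p = 2.53e-08). Of the 25 mesenchymal genes tested, 14 rose and 4 fell (15 and 4 adjusted over the list alone), with a median log2 fold change of 2.94, which was also 2.94 with genes near 0 set at their bounds. The camera test passed at adjusted p = 4.55e-06, and gave adjusted p = 0.0618 with an estimated correlation. The 4 that fell were TWIST1 (-3.65) and SNAI1 (-3.73), both encoding transcription factors that repress E-cadherin, THBS1 (-0.47), the thrombospondin 1 gene, and TPM1 (-0.37), a tropomyosin gene. VIM, the vimentin gene, stayed low, at 2 counts in all of PAR and 1.33 ± 0.489 CPM in TR (ratio 31.8, interval 8.6 to 266; adjusted p = 0.00456). In the basal epithelium list 7 of 10 genes rose and 1 fell, with the same counts adjusted over the list alone (median 2.88, camera adjusted p = 7.51e-11). The faller was the laminin gene LAMA3 (-0.53). ACTA2, the smooth muscle actin gene, rose from 1.93 ± 0.216 to 819 ± 392 CPM (log2 fold change 8.73, SE 0.44), the myosin light chain kinase gene MYLK by 5.67, TRIM29 by 7.005 and TP63, the gene of a basal cell transcription factor, by 4.85. CDH1, which encodes E-cadherin, was higher and not lower in resistant cells (log2 fold change 0.83, SE 0.13; adjusted p = 0.000248), while GRHL2 (-0.97) and ESRP1 (-0.997), regulators of epithelial transcription and splicing, fell. Of 22 epithelial junction genes 1 rose and 6 fell, also adjusted over the list alone (median -0.45, camera adjusted p = 0.184).

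Secretory stress genes were lower in resistant cells, and sterol and replication genes higher. HSPA5, the gene of the endoplasmic reticulum chaperone BiP, fell by 3.08 (SE 0.16) on the log2 scale, from 6982 ± 169 to 823 ± 121 CPM (adjusted p = 5.19e-09), and MANF and HERPUD1, which also respond to unfolded protein, by 2.92 and 2.86. Of the 20 ATF4 and unfolded protein response genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -1.72, camera adjusted p = 9.21e-12). The riser was DDIT4 (2.40), an inhibitor of mTOR signalling that stress also induces. In the cholesterol synthesis list 16 of 23 genes rose and 0 fell (16 and 1 adjusted over the list alone; median 1.45, camera adjusted p = 1.52e-08), led by the sterol sensor gene INSIG1 (3.63, 9.42 ± 1.22 to 116 ± 2.53 CPM), MSMO1 (2.09) and SQLE (1.98). In the S phase list 22 of 27 rose and 0 fell (23 and 1 adjusted over the list alone; median 1.33, camera adjusted p = 7.82e-08), including the replication factor gene MCM10 (3.54) and the cyclin gene CCNE1 (2.42). G2 and mitosis genes did not pass as a list (9 of 26 rose and 2 fell, also adjusted over the list alone; median 0.56, camera adjusted p = 0.211). Of 31 interferon response genes 17 rose and 1 fell, the antiviral GTPase gene MX2 (-1.30), also adjusted over the list alone (median 1.69, camera adjusted p = 1.4e-05). That call was lost with adjusted p = 0.198 with an estimated correlation. OAS2, an antiviral RNA sensor gene, rose by 5.23. In the receptor tyrosine kinase list 8 of 17 fell and 2 rose, also adjusted over the list alone (median -0.36, camera adjusted p = 0.000243; adjusted p = 0.0553 with an estimated correlation); IGF1R, the insulin-like growth factor receptor gene, fell by 6.14, while the collagen receptor gene DDR1 (1.79) and the EGFR ligand gene BTC (1.72) rose. Among 19 p53 targets 6 rose, such as FAS (4.00) and the cell cycle inhibitor gene CDKN1A (2.75), and 2 fell, the stress cytokine gene GDF15 (-3.05) and the pro-apoptotic gene BBC3 (-1.44). The counts were 8 and 2 adjusted over the list alone (median 0.44, camera adjusted p = 0.0223; adjusted p = 0.0618 with an estimated correlation and 0.0501 without the 2 shallowest libraries).

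FGFR1, the gene of a receptor that erdafitinib inhibits (ENSG00000077782, chromosome 8, 38400215 to 38468834), rose from 6.95 ± 1.495 CPM in PAR to 63.0 ± 21.5 CPM in TR (log2 fold change 3.16, SE 0.29; adjusted p = 1.37e-06). FGFR4 rose by 2.91 (SE 0.78; adjusted p = 0.00915), although its libraries overlapped (1.09 ± 0.742 against 8.63 ± 6.12 CPM). FGFR2 rose by 0.46 (SE 0.14; adjusted p = 0.0231), a call lost without PAR 2 (log2 fold change 0.42), TR vehicle 2 (0.46) or TR vehicle 3 (0.36), without a filter on low counts (0.52), with only the 2 groups fitted (0.43) and without the 2 shallowest libraries (0.42). FGFR3 stood at 3.40 ± 3.12 and 6.23 ± 2.23 CPM (adjusted p = 0.244). The FGFR system list, with ligands and co-factors, held 5 risers and 1 faller (FGF13, -3.20, which encodes an intracellular FGF homologue) among 10 genes, also adjusted over the list alone (median 0.63, camera adjusted p = 0.175). Feedback genes of the MAPK pathway went both ways, with 10 of 20 higher and 5 lower (10 and 7 adjusted over the list alone; median 0.80, or 0.70 with bounds; camera adjusted p = 0.497). The immediate early gene FOS fell by 8.30, the ephrin receptor gene EPHA4 by 4.29 and the ERK phosphatase gene DUSP6 by 1.59 on the log2 scale, and PHLDA1 rose by 2.38. The lysosome list (3 of 25 higher and 4 lower, and 3 and 3 adjusted over the list alone; median 0.04 but mean -0.11, camera adjusted p = 0.287) and the YAP target list (5 of 14 higher and 2 lower, also adjusted over the list alone; median 0.19, camera adjusted p = 0.68) did not pass.

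The edgeR quasi-likelihood test called 5818 of 16210 genes (3220 higher, 2598 lower), of which 3888 changed at least 2-fold. Among the most changed were CLEC3A, a C-type lectin gene (ENSG00000166509, chromosome 16, 78022515 to 78066761), at 0.291 ± 0.169 CPM in PAR and 2069 ± 205 CPM in TR (log2 fold change 13.12, SE 0.30; adjusted p = 2.18e-12), and GNAT3, the gustducin gene, with 3 counts in all of PAR and 560 ± 208 CPM in TR (ratio 8136, interval 2780 to 39500). SLIT3 and MPPED1 had 0 counts in PAR and were at least 302-fold and 506-fold higher in TR, against 3 counts over the group. Cancer-testis genes on chromosome X were among the largest falls: CSAG1 fell by 9.003 on the log2 scale from 29.8 ± 4.48 CPM. MAGEA6 (-8.46) and MAGEA3 (0 counts in TR, at least 755-fold lower) are near-identical copies. Reads that matched both were left out by default, so their separate values are uncertain. Of the 38 named genes called, 37 kept the call in each of the 6 fits that left out 1 library and in the 10 other alternatives run for single named genes; FGFR2 was the exception. The test against a 1.5-fold change was not run for them. The count was 3408 with only the 2 groups fitted and 3297 when tested against a 1.5-fold change. Of the 5818 calls, 4564 (without TR vehicle 3) to 5122 (without TR vehicle 1) were kept in fits without 1 library. With only the 2 groups fitted 3399 were kept. Most named genes were picked for large changes or small p in the same fit, so their calls were likely to hold. Resistant cells were also maintained in charcoal-stripped serum with 4-OHT and parental cells in full serum, so the comparison holds selection and growth history together.

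**Figure D3:**
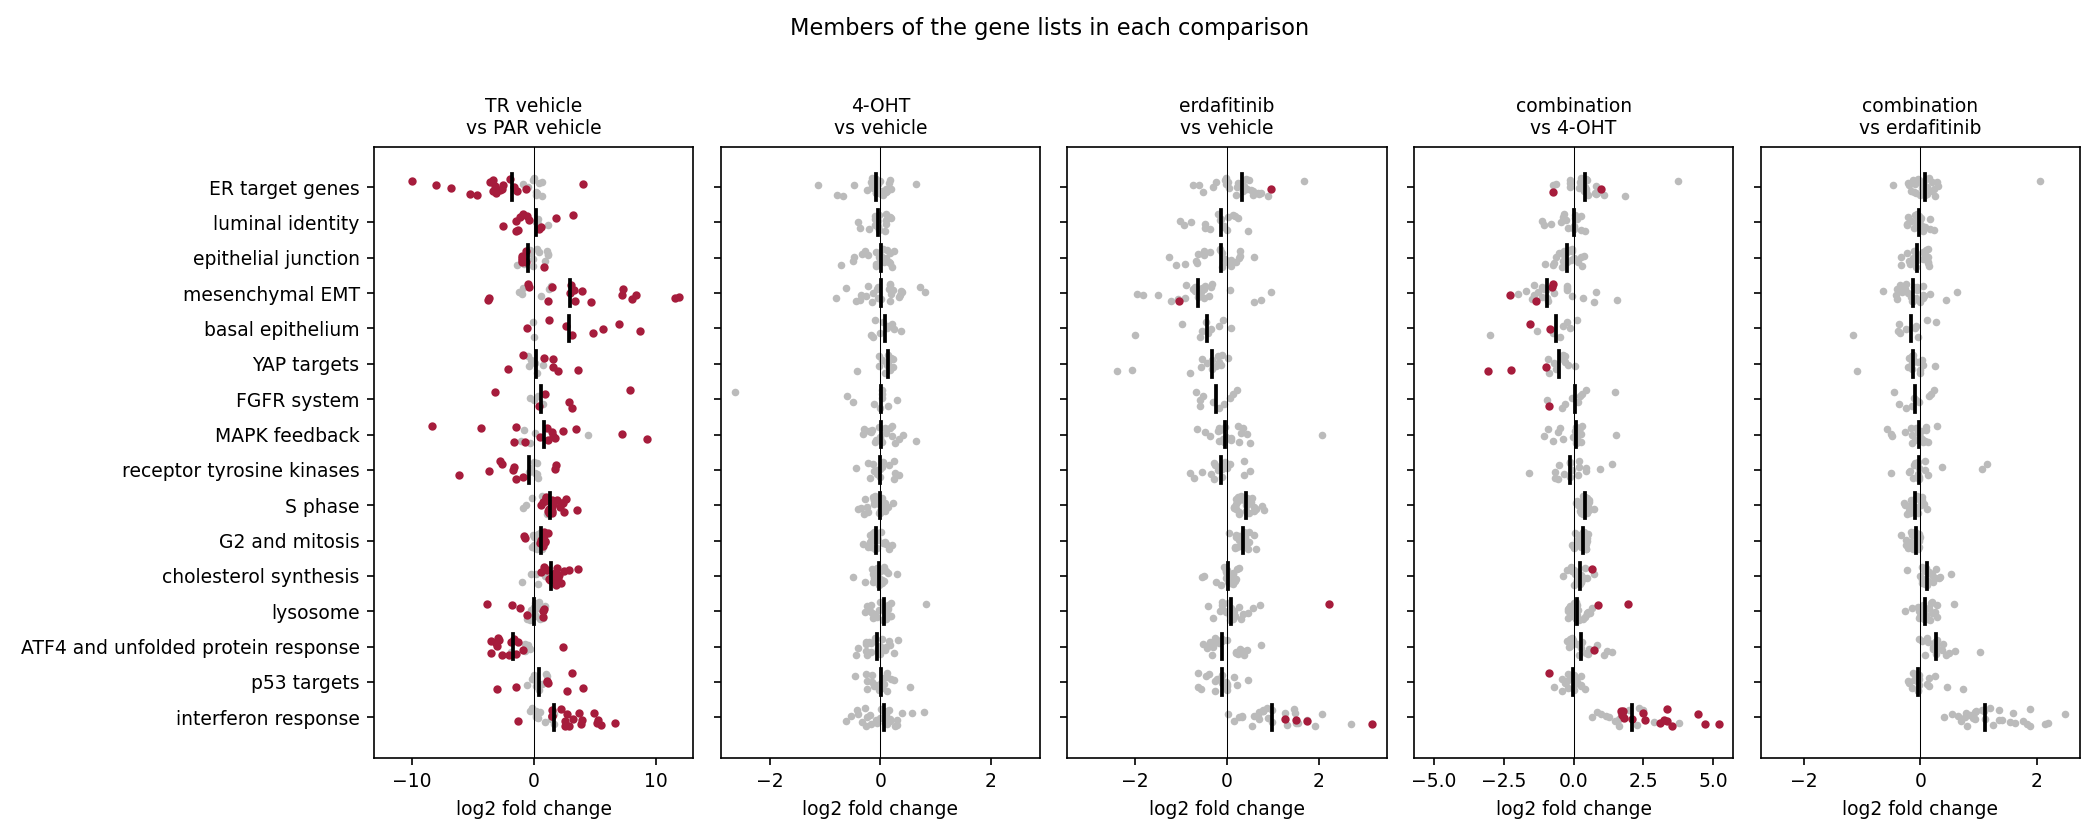
Log2 fold change of each tested member of the 16 gene lists (points, red where called at adjusted p under 0.05) and the list median (black bar), in 5 comparisons with separate axes; members near 0 counts in 1 group have fitted values that are not bounds. ER target genes lie at a median of -1.80 and basal genes at 2.88 in TR vehicle against PAR, and interferon response genes at 2.08 in the combination against 4-OHT.

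Re-exposure of resistant cells to 4-OHT was compared with vehicle, that is, with 4-OHT withdrawn. No gene passed: edgeR called 0 of 16210, with 127 at an unadjusted p under 0.05, and DESeq2 called 0. The 127 are a smaller share than the 0.05 expected if no gene changed, so they are no sign of a hidden response. ESR1 stood at 225 ± 12.4 CPM on 4-OHT and 212 ± 33.7 on vehicle (log2 fold change 0.09, SE 0.15), PGR at 162 ± 16.4 and 157 ± 49.4 (0.04, SE 0.24) and FGFR1 at 62.8 ± 10.5 and 63.0 ± 21.5 CPM (-0.00, SE 0.26). ER target genes as a group had a median of -0.08, with 0 of 28 called, also 0 adjusted over the list alone (camera adjusted p = 0.892). GPNMB, the gene of a lysosomal glycoprotein, stood at 10.5 ± 1.34 CPM on 4-OHT and 5.85 ± 0.661 on vehicle (0.83, SE 0.17; adjusted p = 1), and was the 1 lysosome gene of 25 that passed adjusted over the list alone. The lysosome list passed camera (median 0.07, adjusted p = 0.0151; adjusted p = 0.276 with an estimated correlation), as did YAP targets (median 0.13, adjusted p = 0.0471; adjusted p = 0.187 with an estimated correlation), where 0 of 14 passed, also 0 adjusted over the list alone. The lysosome call was lost without TR vehicle 1 (median -0.12) or TR 4-OHT 1 (-0.00), and the YAP call without TR vehicle 1 (0.05) or 3 (0.09) or TR 4-OHT 1 (0.09) or 2 (0.08). Without the 2 shallowest libraries both were lost (adjusted p = 0.0643 and 0.289). The YAP call was also lost with no filter on low counts (0.107), thinned counts (0.14) and the GC and length correction (0.107). In simulated data with the same depths and spread per gene, 63.1% of 4-fold, 14.5% of 2-fold and 2.5% of 1.5-fold changes were called in this comparison. Genes were drawn independently there. With changes put into the real counts by thinning, the shares were 60.2%, 14.5% and 0.5%. Changes of 2-fold or less were thus rarely detected.

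With erdafitinib alone, GPNMB rose and TIMP3 fell in resistant cells. GPNMB (ENSG00000136235, chromosome 7, 23235967 to 23275108) rose from 5.85 ± 0.661 CPM on vehicle to 27.4 ± 1.64 on erdafitinib (log2 fold change 2.22, SE 0.18), and TIMP3, which encodes a matrix-bound inhibitor of metalloproteinases (ENSG00000100234, chromosome 22, 32801705 to 32863041), fell from 245 ± 19.96 to 80.3 ± 2.88 CPM (-1.61, SE 0.13), both with adjusted p = 5.61e-05 in the quasi-likelihood test. The interferon-induced genes MX1 (1.74), OAS2 (1.51), OAS3 (1.27) and IFI27 (3.16) rose, with adjusted p from 0.0266 to 0.0418, as did the chemokine gene CXCL12 (0.96, adjusted p = 0.00717). The retinaldehyde dehydrogenase gene ALDH1A3 (-1.44), the small heat shock protein gene CRYAB (-2.36) and FN1, the fibronectin gene (-1.05; 86.1 ± 3.20 to 41.5 ± 1.83 CPM), fell. In all, edgeR called 15 genes, 7 higher and 8 lower. The 4 not named by the rule and chosen after their values were seen were LINC00992 (1.29), DIO2 (-2.97), ADGRA2 (-2.56) and CCL28 (-0.81).

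As groups, all 31 interferon response genes had positive log2 fold changes on erdafitinib, 4 rose (17 adjusted over the list alone) and the median was 0.99 (camera adjusted p = 5.27e-46; adjusted p = 0.0012 with an estimated correlation). Of 25 mesenchymal genes 1 fell (6 adjusted over the list alone; median -0.63, adjusted p = 2.62e-14). The S phase list rose with 0 single genes called (4 adjusted over the list alone; median 0.42, adjusted p = 5.74e-15), as did the G2 and mitosis list with 0, also 0 adjusted over the list alone (median 0.35, adjusted p = 5.35e-11; adjusted p = 0.0641 with an estimated correlation). YAP targets fell as a list with 0 of 14 called (4 adjusted over the list alone; median -0.34, adjusted p = 4.56e-09), ANKRD1 and CCN2 standing at -2.07 and -2.41. Basal genes fell as a list with 0 of 10 called, also 0 adjusted over the list alone (median -0.43, adjusted p = 3.18e-05). ER targets rose as a list, with CXCL12 the 1 gene of 28 called (6 higher and 1 lower adjusted over the list alone; median 0.33, adjusted p = 8.89e-08). Lysosome genes rose as a list with GPNMB the 1 gene called (2 adjusted over the list alone; median 0.09, adjusted p = 1.71e-05; adjusted p = 0.0618 with an estimated correlation), a call lost without TR vehicle 1 (median 0.09, adjusted p = 0.0947). ESR1 (0.45, SE 0.15; adjusted p = 0.707), PGR (0.57, adjusted p = 1), FGFR2 (-0.59, SE 0.14; adjusted p = 0.27), FGFR1 (-0.18) and DUSP6 (-0.07) did not pass, and neither did the MAPK feedback list (0 of 20, also 0 adjusted over the list alone; median -0.03 but mean 0.10, adjusted p = 0.497) or the epithelial junction list (0 of 22, also 0 adjusted over the list alone; median -0.13, adjusted p = 0.497).

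The count of 15 genes was small and moved with single libraries. It was 17 without TR vehicle 1, 4 and 2 without TR vehicle 2 and 3, and 3, 3 and 2 without TR erdafitinib 1, 2 and 3, and GPNMB and TIMP3 alone kept the call in all 6 of these fits. CXCL12 lost it without TR vehicle 3 and erdafitinib 3, where its log2 fold change was 0.96 and 0.94, and ALDH1A3, CRYAB, OAS3, FN1, OAS2, MX1 and IFI27 in at least 5 of the 6 fits. Without the 2 shallowest libraries MX1, OAS3 and IFI27 lost it (adjusted p = 0.0556, 0.0556 and 0.0641). With only the 2 groups fitted 0 genes passed, against 26 without a filter on low counts, 2 against a 1.5-fold change and 88 by DESeq2.

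Erdafitinib on top of 4-OHT was compared with 4-OHT alone, the comparison closest to the question in the series title. Interferon-induced genes were among the largest rises. MX1, an antiviral GTPase gene (ENSG00000157601, chromosome 21, 41420020 to 41470071), rose from 43.4 ± 4.81 CPM on 4-OHT to 439 ± 86.8 on the combination (log2 fold change 3.34, SE 0.30; adjusted p = 8.69e-05, quasi-likelihood test). IFI27 rose by 5.19, IFI6 by 4.72, XAF1 by 4.46, IFIT1 by 3.54, HERC6 by 3.35, OAS2 by 2.56 and OAS3 by 2.08. All 31 interferon response genes had positive log2 fold changes, 15 rose (28 adjusted over the list alone) and the median was 2.08 (camera adjusted p = 2.55e-97; adjusted p = 0.000115 with an estimated correlation). Markers of fibroblasts, endothelium, leukocytes and red cells, of which 1 was tested, summed to at most 1.37 CPM in a combination library and 1.98 CPM in any library.

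**Figure D4:**
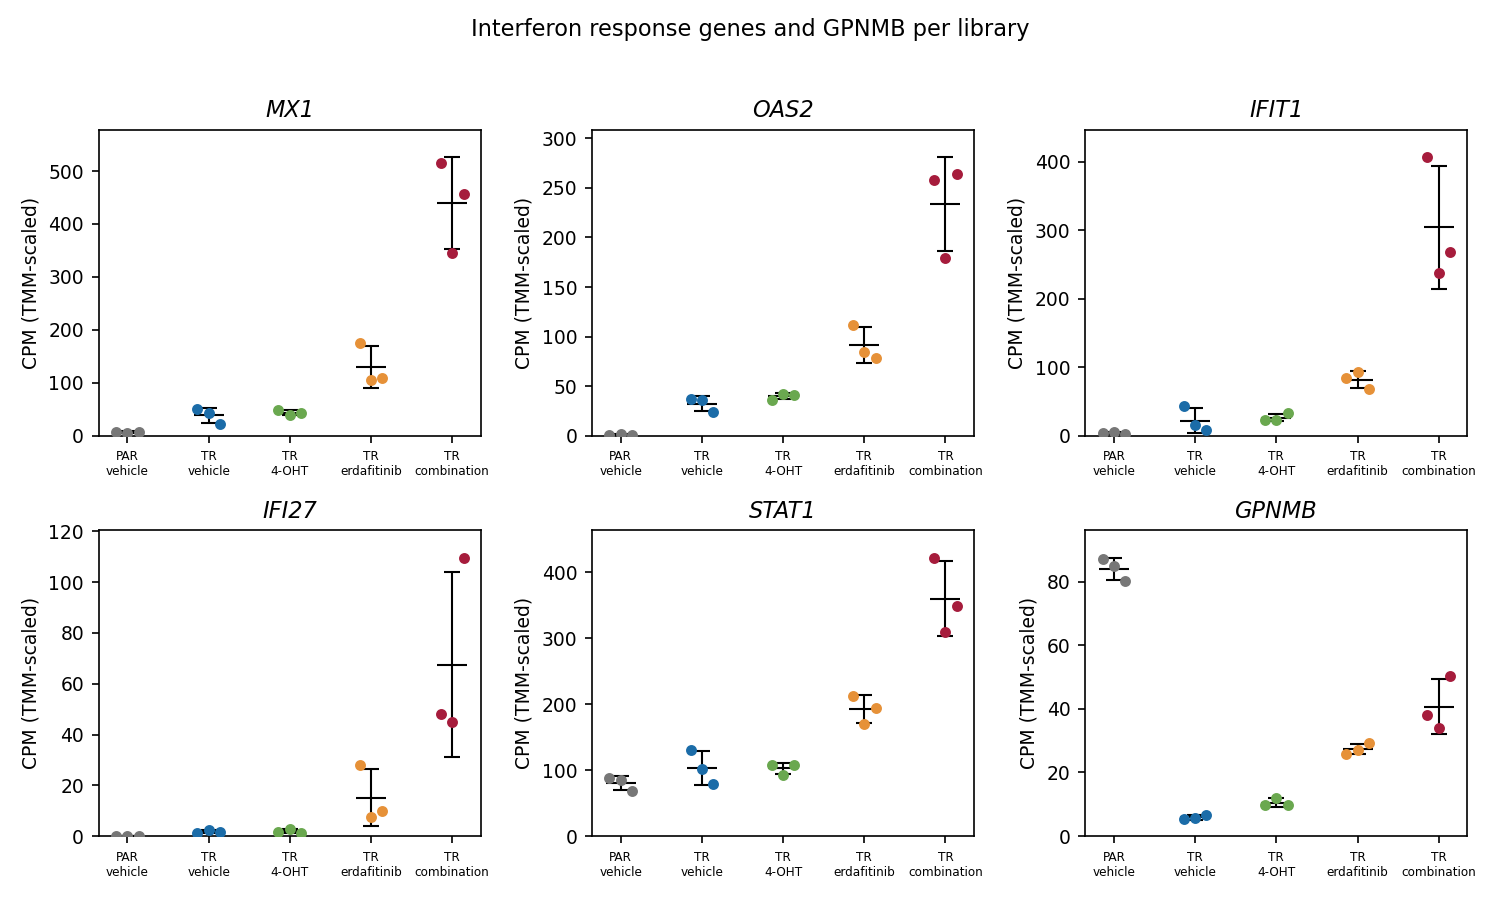
CPM (TMM-scaled) of 5 interferon response genes and GPNMB in the 5 groups, with each library as a point and the mean ± SD (n = 3) as bars. MX1 stands at 43.4 CPM on 4-OHT, 129 on erdafitinib and 439 on the combination.

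Mesenchymal, basal and YAP target genes fell as lists on the combination, with a minority of members called. FN1 fell from 97.0 ± 17.7 to 37.7 ± 6.09 CPM (log2 fold change -1.36, SE 0.16; adjusted p = 0.000758), TPM1 by 0.76 and THBS1 by 0.74 on the log2 scale. Of 25 mesenchymal genes 4 fell (13 adjusted over the list alone; median -0.94, camera adjusted p = 2.42e-14); the other was the collagen gene COL3A1. MYLK (-0.84) and TRIM29 (-1.55) fell in the basal list (2 of 10, and 4 adjusted over the list alone; median -0.63, adjusted p = 1.47e-08), where ACTA2 stood at -1.31 (adjusted p = 0.0877). The YAP targets AMOTL1 (-1.002), ANKRD1 (-2.23) and CCN2 (-3.06), the last of which encodes connective tissue growth factor, fell (3 of 14, and 6 adjusted over the list alone; median -0.51, adjusted p = 1.11e-11). Largest falls were ranked among called protein-coding genes with an average log2 CPM of at least 2 and groups that did not overlap. These were the chemokine gene CCL2 (-2.55), CRYAB (-2.54), the scaffold protein gene NEDD9 (-1.99), ANKFN1 (-1.95) and the sulfatase gene SULF1 (-1.87). FGFR2 fell from 103 ± 10.1 to 56.2 ± 3.00 CPM (-0.87, SE 0.14; adjusted p = 0.0104), a call lost without TR 4-OHT 1 (-0.81), combination 1 (-0.84) or combination 2 (-0.85), and without the 2 shallowest libraries (-0.85).

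ER targets rose as a list, with CXCL12 higher (1.00) and the carbonic anhydrase gene CA12 lower (-0.74) of 28 genes (8 higher and 1 lower adjusted over the list alone; median 0.42, camera adjusted p = 4.4e-06). ESR1 stood at 300 ± 33.0 against 225 ± 12.4 CPM (0.41, adjusted p = 0.399) and PGR at 232 ± 45.8 against 162 ± 16.4 CPM (0.52, adjusted p = 0.559), and GREB1 at 22.8 ± 4.33 CPM, against 486 in PAR. S phase genes (0 of 27, also 0 adjusted over the list alone; median 0.39, adjusted p = 2.5e-06; adjusted p = 0.0618 with an estimated correlation) and G2 and mitosis genes (0 of 26, also 0 adjusted over the list alone; median 0.33, adjusted p = 0.000205; adjusted p = 0.306 with an estimated correlation) rose as lists. So did ATF4 and unfolded protein response genes (PSAT1 of 20, and 4 adjusted over the list alone; median 0.27, adjusted p = 0.00194; adjusted p = 0.0805 with an estimated correlation), lysosome genes (GPNMB, 1.96, and TPP1, 0.87, of 25, and 2 adjusted over the list alone; median 0.11, adjusted p = 0.00514; adjusted p = 0.204 with an estimated correlation) and cholesterol synthesis genes (INSIG1, 0.65, of 23, and 1 adjusted over the list alone; median 0.22, adjusted p = 0.0355; adjusted p = 0.344 with an estimated correlation). Single libraries ended 4 of these calls: the G2 list without combination 1 (median 0.22), the ATF4 list without combination 3 (0.12), the lysosome list without 4-OHT 3 (0.09) or combination 3 (0.06), and the cholesterol list without 4-OHT 2 (0.18), 4-OHT 3 (0.20), combination 2 (0.14) or combination 3 (0.07). The cholesterol call was also lost without the 2 shallowest libraries (adjusted p = 0.0812). MAPK feedback genes did not pass (0 of 20, and 1 lower adjusted over the list alone; median 0.09 but mean -0.04, adjusted p = 0.497), with DUSP6 at 0.16.

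The test called 104 genes, 48 higher and 56 lower. Leaving out TR 4-OHT 1, 2 or 3 gave 51, 63 and 61, and leaving out combination 1, 2 or 3 gave 56, 51 and 45. The call was kept in all 6 of these fits by 11 of the 24 named genes called (MX1, OAS3, OAS2, IFI27, CXCL12, HERC6, FN1, CRYAB, IFIT1, CCL2 and XAF1). Of the other 13, IFI6 lost it without 4-OHT 1 (4.71) or 2 (4.60), TPM1 without combination 3 (-0.69), SULF1 and ANKFN1 without combination 2 or 3, and the rest in 3 to 6 fits. With only the 2 groups fitted SULF1, TPM1, CA12, ANKFN1, NEDD9, THBS1, AMOTL1, MYLK, ANKRD1 and CCN2 lost it. With counts thinned to the lowest total AMOTL1, MYLK, ANKRD1, TRIM29 and CCN2 did. Without the 2 shallowest libraries SULF1, FGFR2, THBS1, AMOTL1, ANKRD1, TRIM29 and CCN2 did, and with no filter on low counts AMOTL1 and MYLK. DESeq2 called 302 genes, 65 passed with only the 2 groups fitted and 33 passed against a 1.5-fold change.

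The combination was also compared with erdafitinib alone. Interferon response genes were higher on the combination as a list, with 31 of 31 positive and a median of 1.11 (camera adjusted p = 7.63e-140; adjusted p = 4.42e-05 with an estimated correlation), although 0 passed singly and 19 passed adjusted over the list alone. MX1 stood at 439 ± 86.8 against 129 ± 39.8 CPM (1.76, SE 0.28; adjusted p = 0.155) and OAS2 at 234 ± 47.3 against 91.6 ± 17.95 CPM (1.35, adjusted p = 0.328). ATF4 and unfolded protein response genes were higher (0 of 20, also 0 adjusted over the list alone; median 0.27, adjusted p = 2.32e-09) and basal genes lower (0 of 10, also 0 adjusted over the list alone; median -0.16, adjusted p = 0.00654), the last a call lost without erdafitinib 1 (-0.18) or combination 3 (-0.26). Another 5 lists passed camera with 0 genes, also 0 adjusted over the list alone, and with medians from -0.13 to 0.11; with an estimated correlation, their adjusted p lay between 0.187 and 0.327. These were G2 and mitosis (-0.07, 0.000868), cholesterol synthesis (0.11, 0.00181), S phase (-0.09, 0.0155), mesenchymal (-0.13, 0.0156) and lysosome genes (0.08, 0.0268), each with its median and adjusted p. Each was lost without combination 3, where the medians were 0.03, 0.00, -0.11, -0.18 and -0.06, and all but the G2 list without at least 1 other library. With no filter on low counts the S phase (adjusted p = 0.0548) and lysosome calls (0.0796) were lost, with thinned counts the mesenchymal (0.114) and lysosome calls (0.0993), and with the GC and length correction the mesenchymal call (0.0793). Over single genes edgeR called 0, with 104 at an unadjusted p under 0.05, while DESeq2 called 18, and 9 passed without a filter on low counts. The 104 are a smaller share than the 0.05 expected if no gene changed. ESR1 (0.05), PGR (-0.01), FGFR1 (-0.25), FGFR2 (-0.14), CDH1 (-0.08) and VIM (-0.01) did not pass.

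Whether 4-OHT altered the response to erdafitinib was tested as an interaction. Over single genes edgeR called 0, with 134 at an unadjusted p under 0.05, and DESeq2 called 1. The 134 are a smaller share than the 0.05 expected if no gene changed. The genes with the smallest p were LAMP3, the gene of a lysosomal membrane protein (log2 difference 1.84, SE 0.34), MX1 (1.59, SE 0.39), B2M, the β2-microglobulin gene (0.90, SE 0.22), DDX60 (1.49, SE 0.39) and ZNF710-AS1 (-1.10, SE 0.29), each with adjusted p = 1. The interferon list passed, with 31 of 31 genes positive, a median difference of 1.20 and 11 genes adjusted over the list alone (camera adjusted p = 1.8e-43; adjusted p = 0.0012 with an estimated correlation). Camera calls that held with an estimated correlation were those of the ER target, basal, ATF4 and unfolded protein response, cholesterol and S phase lists for resistance and 0 of 2 for 4-OHT. For erdafitinib alone they were those of the interferon, S phase, mesenchymal, YAP, ER target and basal lists. They were those of the interferon, mesenchymal, YAP, basal and ER target lists for the combination against 4-OHT, and those of the interferon, ATF4 and basal lists for the combination against erdafitinib and for the interaction. The fry test lost the lysosome and YAP calls for 4-OHT, the lysosome call for erdafitinib alone, the G2, cholesterol and lysosome calls for the combination against 4-OHT. It lost all but the interferon call for the combination against erdafitinib and for the interaction, with the ATF4 list at adjusted p = 0.0626 and 0.126 and the basal list at 0.157 and 0.0916.

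The change with erdafitinib was similar in direction with and without 4-OHT. All 15 genes called for erdafitinib alone were also called in the same direction for the combination against 4-OHT, where independent lists would share 0.05. Over 16210 genes the log2 fold changes had a Pearson r of 0.491 and a Spearman rho of 0.492, across genes, which are not independent replicates, and these comparisons share no library. The value was 0.107 without a filter on low counts and 0.258 without TR 4-OHT 1.

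The overlap with the resistance change was examined last. Of the genes called both for TR against PAR and for the combination against 4-OHT, which share no library, 62 went in opposite directions and 21 in the same direction, where independent lists would give 18.8 and 18.5. Higher in resistant cells and lower with the combination were 44 genes (11.1 for independent lists), among them TIMP3, CCL2, CRYAB, ALDH1A3, FN1, MYLK and TRIM29. Lower in resistant cells and higher with the combination were 18 genes (7.69), among them GPNMB, CXCL12, LAMP3 and TPP1. The interferon genes IFI27, OAS2, MX1 and IFIT1 were among the 16 that were higher in both (9.53). Over all tested genes the correlation was weak (Pearson r -0.102, Spearman rho -0.151, across genes). The opposite count was 28, 39 and 33 without TR 4-OHT 1, 2 and 3, 28, 28 and 24 without combination 1, 2 and 3, and 31 with only the groups compared. For erdafitinib alone, which shares the TR vehicle libraries with the resistance comparison, 10 genes were opposite and 4 the same, against 2.71 and 2.67 for independent lists, with r -0.166 and covariance -0.115. Without TR vehicle 2 or 3 or erdafitinib 1, 2 or 3 the opposite count was 4, 2, 3, 3 and 2 and the same-direction count 0. With only the groups compared both were 0. The opposite count was 56 with DESeq2, 18 with no filter on low counts, 87 with the GC and length correction and 373 with the axis covariate. The covariance was -0.558 with no filter, -0.248 without TR vehicle 1 and -0.187 without PAR 3. All libraries were also redrawn in 10 simulations, with the erdafitinib group given the TR vehicle means and so unchanged. There r averaged -0.123 (range -0.145 to -0.0978) and the covariance -0.106 (range -0.125 to -0.0829), with at most 1 opposite gene. The observed covariance lay within its simulated range and the observed r outside. Genes were drawn independently, without the axis that libraries share. The simulated ranges may therefore be too narrow, and these positions decide nothing. With 3 shared controls no split into parts of at least 2 was possible, so part of the excess may come from the shared controls.

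**Figure D5:**
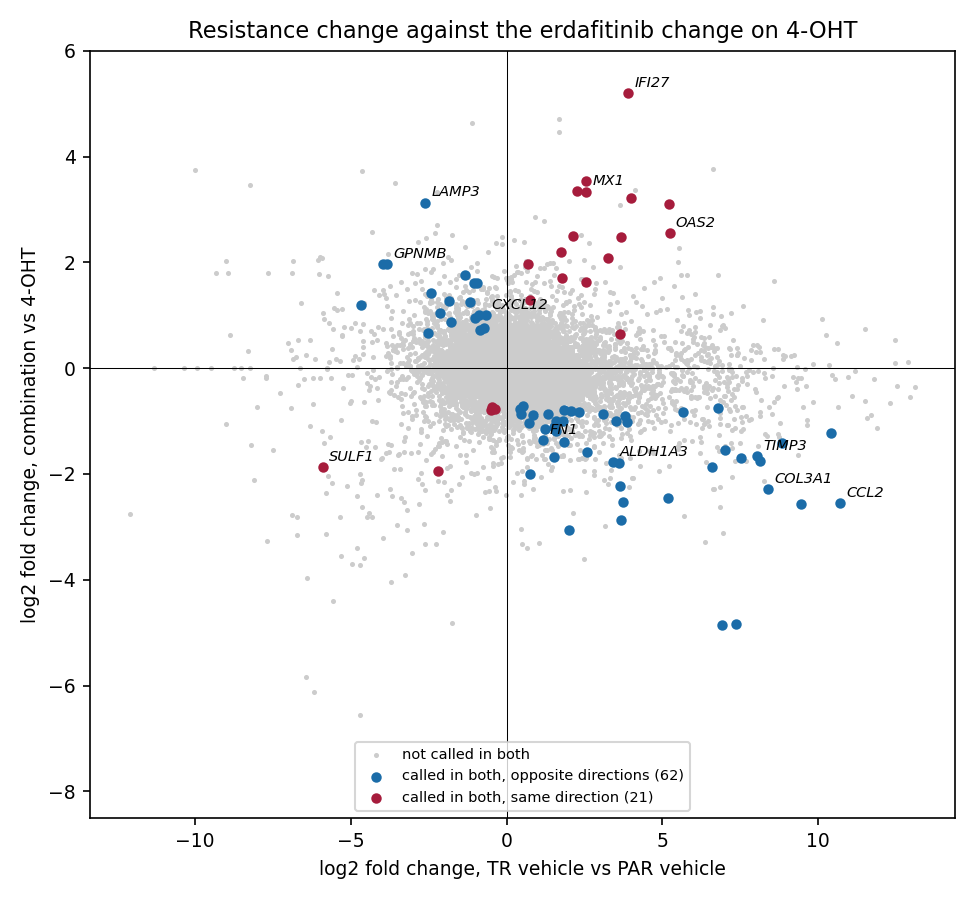
Log2 fold change of the 16210 tested genes for TR vehicle against PAR vehicle (x) and for the combination against 4-OHT (y), with genes called in both in opposite directions in blue (62) and in the same direction in red (21). Genes at 0 counts in PAR, such as CCL2 and COL3A1, have fitted x values that are not bounds.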

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

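The tests of GC content, for the axis within groups and for the interferon genes, were chosen only after the result was seen. Lists of genes were picked out here where the erdafitinib change with 4-OHT differed from that without it, by camera on the interaction of the edgeR fit. The median differences in log2 fold change were 1.20 for interferon response genes (adjusted p = 1.8e-43; adjusted p = 0.0012 with an estimated correlation), 0.295 for ATF4 and unfolded protein response genes (adjusted p = 0.000205; 0.049 with an estimated correlation) and -0.277 for basal genes (adjusted p = 0.00274; 0.0303 with an estimated correlation). They were -0.211 for YAP targets (adjusted p = 0.00514; adjusted p = 0.0672 with an estimated correlation) and -0.162 for mesenchymal genes (adjusted p = 0.0306; adjusted p = 0.344 with an estimated correlation). The YAP call was lost without TR combination 3 (median -0.24, adjusted p = 0.12) and with counts thinned to the lowest total (adjusted p = 0.065). The mesenchymal call was lost without TR vehicle 1 (-0.05), TR 4-OHT 1 (-0.04), erdafitinib 1 (-0.16), combination 1 (-0.17) or combination 3 (-0.28), with no filter on low counts (adjusted p = 0.11), with thinned counts (0.226) and with the GC and length correction (0.164). Of these 5 calls only that of the interferon list held by fry (adjusted p = 0.00468). Over single genes the interaction test of edgeR called 0, with 134 at an unadjusted p under 0.05, and DESeq2 called 1. The 134 are a smaller share than the 0.05 expected if no gene changed.

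The rise of interferon response genes with erdafitinib on 4-OHT (median log2 fold change 2.08) was weighed against 3 technical explanations. The tables argue against each, for cells of another type only as far as the markers reach. After the GC and length correction the median was 2.179. Markers of other cell types summed to at most 1.37 CPM in a combination library, against 1.05 in a 4-OHT library. They cover fibroblasts, endothelium, leukocytes and red cells, and cannot decide on other epithelial cells. The lowest median without 1 library was 1.909. A response of the cells to the drugs may account for it, which stays a hypothesis found and tested on the same data, and what would start such a response was not tested.

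Libraries of the same group differed along 1 axis whose gene loadings followed transcript GC content (Spearman 0.809). After thinning to the lowest total the axis still held 70.9% of the within-group variance, which argues against an effect of count totals on the calculation. Thinning keeps any GC bias already in a library, so it cannot decide whether such a bias came with a low yield. In PAR, TR vehicle, TR 4-OHT and TR erdafitinib the library with the lowest total also had the lowest score (-0.316, -0.596, -0.164 and -0.228). In TR combination the library with the lowest total, replicate 3, had the highest score (0.335). Sequencing depth in that sense stays open. The axis held 71.9% without the 37 mitochondrial genes. With 10590 genes on the axis little change was likely by construction, so this cannot decide on the share of mitochondrial reads. In each group, libraries with a positive score on the axis had a lower mitochondrial share than those with a negative score. The highest score was 0.496 in PAR 3, with a share of 14.5%, and the lowest -0.596 in TR vehicle 1, with 22.6%. The share of mitochondrial reads therefore stays open. A GC-dependent step in making the libraries fits the values and could be the source, but the labels give no batch, and no biological explanation was tested.

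The 0 genes called for 4-OHT against vehicle fit low power, since 14.5% of simulated 2-fold changes were called. Changes hidden by the shallow library TR 4-OHT 2 are argued against only where they are large enough for 2 libraries against 3, since leaving it out also gave 0 genes called (33 at an unadjusted p under 0.05, against 127), while that fit called 63 for the combination against 4-OHT. Both 33 and 127 are smaller shares of the tested genes than the 0.05 expected if no gene changed. The lower ESR1 expression of resistant cells (log2 fold change -1.44) fits as well and may leave less receptor for 4-OHT to act on. These 2 explanations stay open, as do smaller changes hidden by that library. Other explanations were not tested.

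Other splits of the same libraries into groups of 3 are too few, at 10, for a share under 0.05. For TR against PAR the real grouping called most, 1 of 10 splits reaching 5818, and the highest other gave 3022 with PAR 1, PAR 2 and TR vehicle 1 set against the rest. In these 3 libraries the highest-GC genes lay below their group mean in log2 CPM (-0.268, -0.509 and -0.976). In PAR 3, TR vehicle 2 and TR vehicle 3 they lay above it (0.778, 0.498 and 0.477). That split therefore also set 1 end of the GC axis against the other. For erdafitinib against vehicle 1 of 10 splits reached 15 and for the combination against 4-OHT 1 of 10 reached 104, with 0 in every other split. For 4-OHT against vehicle and for the combination against erdafitinib the real split and every other of the 10 gave 0 in edgeR. In the real splits 127 and 104 genes had an unadjusted p under 0.05, fewer than expected if no gene changed, and DESeq2 called 0 and 18. For the interaction the real grouping also gave 0, so that all 60 of 60 groupings of the 12 resistant libraries (the real one and others drawn at random) reached it by construction. A real count of 0, here and in the 2 comparisons before, says nothing about chance. The highest other grouping gave 3670 and the next 415, which points to some structure of the samples, but what set these 2 apart was not tested.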

How the results depend on the processing

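Tests with the GC and length correction, with the first within-group axis as a covariate and without the 2 shallowest libraries were chosen only after the result was seen. The axis covariate was taken from the within-group deviations of these same libraries. It removes spread within groups and can hardly shift the differences between groups. With it the common biological coefficient of variation was 12.6%, against 30.8%. More calls with it were therefore likely by construction and add no support. The GC and length correction also lowered the common biological coefficient of variation, to 19.3%, so more calls with it may follow from the smaller spread. The test against a 1.5-fold change asks for more and so calls fewer genes. For every other value that moved, the cause was not tested, except that only the groups compared and left-out libraries leave fewer samples. TR against PAR (5818 genes) gave 3408 with only the groups compared, 3297 against a 1.5-fold change and 9368 with the axis covariate, and 4695 to 6266 without 1 library. Erdafitinib against vehicle (15) gave 88 with DESeq2, 26 with no filter, 0 with only the groups compared, 2 against a 1.5-fold change, 158 with the GC correction and 637 with the axis covariate, and 2 to 17 without 1 library. The combination against 4-OHT (104) gave 302 with DESeq2, 65 with only the groups compared, 33 against a 1.5-fold change, 460 with the GC correction and 1538 with the axis covariate, and 45 to 63 without 1 library. The combination against erdafitinib (0) gave 18 with DESeq2, 9 with no filter, 6 with the GC correction and 34 with the axis covariate, and the interaction (0) gave 1 with DESeq2. Genes opposite in resistance and the combination (62) numbered 182 with DESeq2, 31 with only the groups compared, 285 with the GC correction and 905 with the axis covariate, and 24 to 82 without 1 library. The correlation of the erdafitinib changes with and without 4-OHT (0.491) was 0.406 with DESeq2, 0.107 with no filter, 0.580 with only the groups compared and 0.572 without the 2 shallowest libraries, and 0.258 to 0.559 without 1 library.

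With the replicate number as a block the counts were 5549, 0, 9, 76, 0 and 0 in the order of the report, and 40 opposite genes. The block ended 8 calls of named genes, among them OAS3, OAS2 and IFI27 for erdafitinib (adjusted p = 0.0886, 0.0886 and 0.169) and MYLK, ANKRD1, TRIM29 and CCN2 for the combination against 4-OHT (0.0526, 0.0538, 0.0985 and 0.0536). The deviations of the libraries from their group means showed no pairing by number. Of 30 pairs with the same number 14 correlated over 0.1 (range -0.951 to 0.919), and 6 of 15 libraries correlated best with their own number. The GC axis held 73.4% of the variance of these deviations, so a pairing beneath it could be hidden. The G2 and mitosis list turned direction in the combination against erdafitinib without TR combination 3 (median 0.032 against -0.07, and -0.248 to 0.032 without 1 library, adjusted p = 0.833 by camera on the edgeR fit). Of called named genes, 37 of 38, 2 of 11 and 11 of 24 kept the call in every fit without 1 library, for TR against PAR, erdafitinib and the combination against 4-OHT. The percent of called genes that were higher moved by over 10 points for erdafitinib (46.7%) with the block (33.3%), without the 2 shallowest libraries (26.7%) and without TR erdafitinib 1 or 2 (66.7% of 3 genes each), and for the combination against 4-OHT (46.2%) against a 1.5-fold change (63.6%) and without combination 2 (60.8%) or 3 (62.2%). Depth limits genes below 0.432 CPM in the shallowest library, and with counts thinned to the lowest total 176 of the named-gene results kept their side of the threshold.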

Other observations

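The test of the genes around FGFR1 was chosen before its result was seen, and the genes of this and the next paragraph were chosen after their values were seen. Some single genes outside the interferon list were also called higher with the combination against 4-OHT (edgeR quasi-likelihood test), and were not tested as a group. B2M, the shared chain of class I molecules, stood at 201 ± 26.1 CPM on 4-OHT and 573 ± 123 on the combination (log2 fold change 1.51, SE 0.16; adjusted p = 0.000284). The dendritic cell lysosome gene LAMP3 rose by 3.13 (adjusted p = 5.66e-05), the scramblase gene PLSCR1 by 1.98 (adjusted p = 0.000665), the nuclear body gene SP100 by 1.62 (adjusted p = 0.0126) and the nucleotide hydrolase gene SAMHD1 by 0.97 (adjusted p = 0.00589). HLA-B (0.93, adjusted p = 0.612) and the peptide transporter gene TAP1 (0.23, adjusted p = 0.959) did not pass, and reads of HLA-B depend on the allele.

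Some single genes outside the lists were called lower with the combination against 4-OHT (edgeR), and were not tested as a group. IVL, which encodes involucrin of the cornified envelope, went from 9.88 ± 4.38 to 1.33 ± 0.105 CPM (-2.87, adjusted p = 0.0101), and the protocadherin gene FAT2 fell by 1.71 (adjusted p = 0.00589). MIR205HG, host of a microRNA of basal cells, fell by 1.01 (adjusted p = 0.00589) after a log2 fold change of 3.88 in TR against PAR, and TGFB2, a TGF-β ligand gene, by 1.58 (adjusted p = 0.0114) after 2.58. In the other direction, GPNMB, TPP1 and RRAGD stood at -3.84, -1.78 and -1.84 in TR against PAR and rose with the combination by 1.96, 0.87 and 1.27 (adjusted p = 8.69e-05, 0.022 and 0.00797).

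As a hypothesis, a copy gain of the FGFR1 region could account for the higher FGFR1 in resistant cells. The other 23 tested genes within 1 Mb had a median log2 fold change of 0.194 (bootstrap SE 0.187), with 6 higher and 3 lower, which argues against a gain of the whole region. A smaller gain, of FGFR1 itself or on 1 side, stays open. RPS20P22 (2.87) and LETM2 (1.06), which lie within or overlap FGFR1 (3.16), and on the side of higher coordinates ENSG00000253361 (1.75), PLEKHA2 (1.95) and ADAM9 (1.97) were higher in TR. On that side TM2D2 (0.597) was higher by less, and TACC1 (0.511, adjusted p = 0.0672) and ADAM32 (1.745, adjusted p = 0.128) did not pass. DNA copy number was not analysed here.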
